A study of Homo sapiens with 2 samples.

How the data were processed

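Chromatin of VCaP cells was crosslinked with formaldehyde and sonicated, part of it was kept as input, and the rest was immunoprecipitated with an antibody against SOX9, per the labels' protocols. Libraries were amplified by PCR, selected by size on a gel and sequenced on an Illumina Genome Analyzer, per the labels' protocols. The submitters' processing notes name the genome build hg18 and the software CASAVA, version 1.8.2. The aligner, the peak caller, its threshold, and whether the SOX9 peaks were called against the input library are not given in the sources used here.

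The deposited files were 2 peak lists without header lines, 1 per library, with 5 columns giving the chromosome, start, end, name and score of each peak. What the score deposited by the authors measures, and on which scale, is not given in the sources used here. The smallest scores were 1.33 in the SOX9 list and 1.43 in the input list, both just above 1.30, which is the value of −log10(0.05), but no source states that the score is a log p or q value. Scores were therefore used only to describe, rank or filter peaks within 1 list. Starts were converted from 0-based to 1-based positions for reporting. The positions were checked against the build: the last peak on chromosome 19 ended at 63776293, and 41 peaks on that chromosome lay beyond the last gene that the GRCh38.p14 gene table lists for it. That gene table was the only reference used here and its build differs from the files, so none of its positions was used beyond this check. Genomic location, sequence motifs and gene lists, which had been planned before the data were examined, were not run for this reason, and liftover between builds was not attempted.

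The labels assign 1 library to SOX9 ChIP and 1 to input. Every value is a description of these 2 lists. Shares of peaks have exact Clopper-Pearson 95% intervals and counts have exact Poisson 95% intervals, which treat peaks as independent and cover counting error only. PCR-amplified reads without molecular identifiers are not independent molecules, and the read depth of both libraries is unknown.

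Peaks were taken to overlap when they shared at least 1 bp. For random placement each peak kept its width and chromosome and was moved to a uniformly drawn position between the chromosome start and the last peak end of either list, 1000 times. Unassembled or unmappable sequence was not excluded, since no genome was used. Clusters were runs of 3 or more peaks separated by at most 12.5 kb. The counting of overlaps and clusters was checked on simulated data. In a list of 7741 peaks, 200 of 200 peaks planted on input peaks were recovered, and 50 of 50 planted clusters were recovered in a list of 7747. The planted items met the definitions by design, so this checks the counting only. Peaks singled out by position followed a rule set before the data were examined, namely the 10 highest-scoring SOX9 peaks, the 3 highest-scoring input peaks, the 3 widest SOX9 peaks and the 3 SOX9 clusters with the most peaks. The windows of 5 Mb, the density per Mb and the input clusters were added after the data had been seen. So were the 60 to 70 Mb stretch of chromosome 11, the naming of smaller SOX9 clusters and the spacing of neighbouring peaks. The same holds for the joined regions per chromosome, the placement of neighbouring peaks as units and the random subsets of peaks.

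The following settings, chosen before the data were examined, were varied: an overlap of at least 50% of the SOX9 peak, centres within 1000 bp, peaks scoring at or above the list median, the 1000 highest-scoring peaks, nuclear chromosomes only, removal of SOX9 peaks that overlap input, merging of peaks within 500 bp, and cluster gaps of 5000 and 25000 bp. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.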

Results

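SOX9 occupancy was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in VCaP, an established human prostate cancer cell line that carries the TMPRSS2-ERG gene fusion and expresses SOX9 at a high basal level. SOX9 is a transcription factor whose HMG-box domain binds DNA, and the series places it in the context of the WNT signalling pathway in prostate cancer. The data comprised 1 SOX9 ChIP library and 1 input library, the latter made from sonicated VCaP chromatin that was not immunoprecipitated. Each library was represented by 1 list of peaks in hg18 coordinates, each peak with a position and a score. The names of the SOX9 peaks carry the replicate number 2, so the list may be 1 of several replicates, of which others were not analysed here. With 1 library per group, replicate error could not be measured, so intervals given here cover counting error over peaks only and no p-value was computed. The number of reads behind the lists is unknown. Genes, promoters and sequence motifs under the peaks, WNT pathway genes included, were not analysed here because no hg18 genome or annotation was used, and the regions are therefore identified by position.

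The first comparison asked how many regions were called as enriched with the SOX9 antibody and in input chromatin. The SOX9 library yielded 7547 peaks and the input library 401, so the SOX9 list was 18.8 times as long. SOX9 peaks covered 4.13 Mb in total, against 0.104 Mb for input peaks. SOX9 peaks were also wider, with a median of 413 bp (quartiles 298 and 654 bp) against 219 bp (quartiles 155 and 267 bp). Of the SOX9 peaks, 811 (10.7%) were at least 1000 bp wide, compared with 5 input peaks (1.25%). The shortest SOX9 peak was 243 bp and 597 peaks had exactly that width, whereas the shortest input peak was 138 bp, a width shared by 25 peaks. The lower bound on peak width thus differed between the lists. Widths and covered lengths are therefore not compared on equal terms. Whether calling settings also affected the numbers of peaks is unknown.

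Peak scores spanned a wide range within the SOX9 list, from 1.33 to 602 with a median of 7.94 and quartiles of 4.92 and 19.8. Across SOX9 peaks, score and width were correlated (Spearman's rho = 0.67). The corresponding rho across input peaks was 0.61. Both are correlations across peaks of a single library, and peaks are not independent replicates.

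The 10 highest-scoring SOX9 peaks had scores from 342 to 602, against a list median of 7.94, and 0 of the 10 overlapped an input peak. Only 0.530% of the whole list overlapped one, so 0 of 10 says little about strong peaks. The highest score, 602, belonged to a peak of 1260 bp on chromosome 15 (96304430 to 96305689). It was followed by a 758 bp peak on chromosome 9 (130882721 to 130883478) with a score of 511. Chromosome 11 held 3 of the 10. These lay at 63709141 to 63710650 with a score of 471, at 67031964 to 67032765 with a score of 429, and at 550623 to 551284 with a score of 362. The fifth-ranked peak was on chromosome 7 (149706974 to 149707712) and had a score of 402. Chromosome 1 contributed a peak of 2176 bp at 16891423 to 16893598 with a score of 384 and a peak of 557 bp at 1324389 to 1324945 with a score of 342. The remaining members of this set were a peak on chromosome 17 (45221267 to 45221863), with a score of 377, and a peak on chromosome 19 (54961375 to 54962198), with a score of 355. The widest SOX9 peaks were found on chromosome 4 (186175113 to 186179033, 3921 bp, score 160), chromosome 6 (165994032 to 165997854, 3823 bp, score 79.5) and chromosome 19 (1417504 to 1420919, 3416 bp, score 82.9).

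The highest-scoring input peak was at 119600188 to 119600481 on chromosome 6, with a score of 137 on the input list's own scale. The next were a 1418 bp peak on chromosome 1 at 121185596 to 121187013, with a score of 130, and another on chromosome 1 at 91625308 to 91625797, with a score of 123.

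The second comparison asked which SOX9 peaks lay where input chromatin was itself enriched. Of the 7547 SOX9 peaks, 40 shared at least 1 bp with an input peak, a share of 0.530% (exact Clopper-Pearson 95% interval 0.379 to 0.721%). Seen from the other list, 40 of the 401 input peaks (9.98%, interval 7.22 to 13.3%) were overlapped by a SOX9 peak. Whether the SOX9 peaks were called against the input library is not known, and such calling would itself lower the overlap. When single SOX9 peaks were placed at random on their own chromosomes 1000 times, a mean of 4.42 and at most 9 overlapped an input peak. Mitochondrial DNA held 8 peaks of each list and contributed 5 of the 40 overlapping SOX9 peaks. Random placement there was confined to 16571 bp, where overlap by placement alone is frequent, so these 5 are not taken as an excess. Nuclear chromosomes contributed the other 35, which was 0.464% of 7539 nuclear SOX9 peaks (interval 0.324 to 0.645%). Single placement breaks up groups of peaks, and 6 of the overlapping peaks came from a single cluster on chromosome 2. Nuclear SOX9 peaks up to 12.5 kb apart were therefore also moved together as 5946 units. Of these units 23 held an overlapping peak, compared with a mean of 0.671 and at most 6 in 1000 random placements. Counted as peaks, 35 overlapped, against a mean of 0.696 and at most 6 in these placements. The mean of 4.42 for single peaks over all chromosomes was thus probably mostly mitochondrial. The overlapping peaks had a median score of 10.8 (quartiles 7.26 and 17.8) and none scored above 52.3, while peaks without overlap had a median of 7.94 and reached 602. These sets held 40 and 7507 peaks, and the maximum of a smaller set tends to be lower by size alone. Among the 1000 highest-scoring SOX9 peaks, 2 overlapped an input peak (0.200%, interval 0.0242 to 0.721%), an interval that includes the share of the whole list.

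The distribution over chromosomes was then compared between the lists. SOX9 peaks were found on all 22 autosomes, X, Y and mitochondrial DNA. Chromosome 1 held the most, with 666 peaks (8.82% of the list, interval 8.19 to 9.49%), followed by chromosome 11 with 567 (7.51%, 6.93 to 8.13%), chromosome 19 with 534 (7.08%, 6.51 to 7.68%) and chromosome 17 with 517 (6.85%, 6.29 to 7.44%). Chromosomes 11, 17 and 19 together carried 21.4% of the SOX9 peaks. Chromosome 17 carries SOX9 itself and AXIN2, a feedback inhibitor of WNT signalling, and chromosome 19 is gene-dense and carries KLK3, which encodes prostate-specific antigen. Whether any peak lies at these genes was not analysed here. The X chromosome held 88 SOX9 peaks (1.17%, 0.936 to 1.43%), and Y held 14. Among the 1000 highest-scoring peaks 6 were on X.

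The order was different once length was taken into account. The number of copies of each chromosome in VCaP was not measured, so peaks per Mb are not corrected for it and do not measure binding alone. Relative to the length between the start of each chromosome and the last peak of either list, chromosome 19 had 8.37 SOX9 peaks per Mb (exact Poisson 95% interval 7.68 to 9.11) and chromosome 17 had 6.57 (6.02 to 7.17). Chromosome 11 had 4.24 (3.90 to 4.61) and chromosome 20 had 4.21 (3.72 to 4.75), against 2.45 over all nuclear chromosomes. Low densities among the autosomes were found on chromosomes 13 (1.41, 1.20 to 1.65), 18 (1.47, 1.21 to 1.77), 4 (1.5, 1.33 to 1.69) and 16 (1.76, 1.49 to 2.06). The X chromosome was lower still at 0.571 peaks per Mb (0.458 to 0.704). These values count stretches before the first peak of a chromosome. Measured from the first to the last peak of either list, chromosome 13 had 1.69 peaks per Mb (1.44 to 1.98), while chromosome 22 rose from 3.30 to 4.86 (4.15 to 5.67) and chromosome 21 from 3.77 to 4.76 (4.08 to 5.51), with 8.40 on chromosome 19 and 6.58 on chromosome 17. Chromosome 19 was also over-represented among strong peaks. It held 112 of the 1000 highest-scoring peaks, so that 20.97% of its peaks were in that set (interval 17.6 to 24.7%), compared with 13.3% of the list as a whole.

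Input peaks were spread differently, although most of them lay in tight groups, so that their intervals are too narrow. Chromosome 2 held 48 of the 401 input peaks (12.0%, interval 8.96 to 15.6%), chromosome 10 held 40 (9.98%, 7.22 to 13.3%), Y held 37 (9.23%, 6.58 to 12.5%) and chromosome 16 held 36 (8.98%, 6.37 to 12.2%). The SOX9 shares were 6.24% for chromosome 2 (5.71 to 6.81%), 4.19% for chromosome 10 (3.75 to 4.66%), 0.186% for Y (0.101 to 0.311%) and 2.05% for chromosome 16 (1.75 to 2.40%). On chromosomes 1, 11 and 19 input peaks made up 3.99%, 2.49% and 2.74% of their list. Groups of neighbouring peaks weighed on these shares, so peaks up to 12.5 kb apart were also joined, which left 161 input and 5947 SOX9 regions. Chromosomes 2, 10 and 16 then held 6, 9 and 7 of the 161 input regions, and chromosomes 1, 11 and 19 held 10, 5 and 5, with intervals that overlapped those of the SOX9 regions in all 6 cases. Y held 10 joined input regions (6.21%, 3.02 to 11.1%) against 0.151% of SOX9 regions (0.0692 to 0.287%). X held 16 (9.94%, 5.79 to 15.6%) against 1.28% (1.01 to 1.60%), and chromosome 4 held 14 (8.70%, 4.84 to 14.2%) against 4.09% (3.60 to 4.62%). Chromosome 15 held no input region (interval 0 to 2.27%) against 4.10% of SOX9 regions (3.61 to 4.64%). The intervals of the other chromosomes overlapped.

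**Figure D1:**
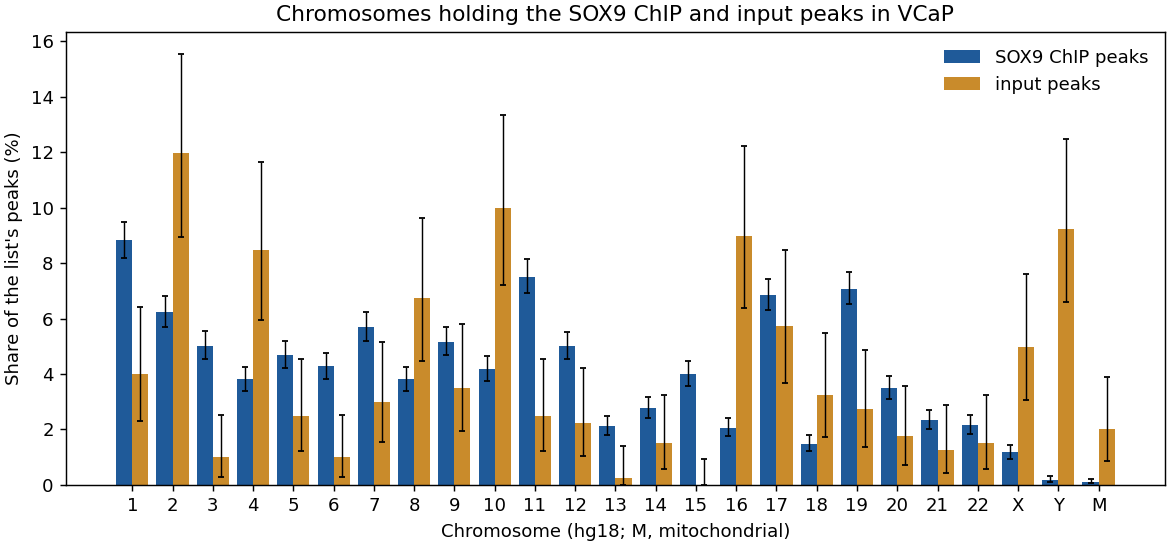
Share of each list's peaks (y axis, %) on each chromosome (x axis, hg18), for the 7547 SOX9 ChIP peaks and the 401 input peaks; error bars are exact 95% intervals for counting error. Chromosomes 1, 11, 17 and 19 hold the largest SOX9 shares, from 6.85% to 8.82%, whereas input peaks are most frequent on chromosomes 2, 10, Y and 16.

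Within chromosomes, SOX9 peaks were concentrated in particular stretches. In windows of 5 Mb the median was 8 peaks over 627 windows, and 61 windows held none. The 10 fullest windows held 880 peaks, 11.7% of the list. The 2 fullest were adjacent on chromosome 11, with 150 peaks between 60 and 65 Mb (Poisson interval 127 to 176) and 129 peaks between 65 and 70 Mb (108 to 153). No window on another chromosome held more than 86. That number was reached on chromosome 9 in the window from 135 Mb. It was followed by 83 peaks on chromosome 19 between 50 and 55 Mb, 82 on the same chromosome between 0 and 5 Mb, and 81 on chromosome 17 from 75 Mb. The last window of a chromosome is shorter than 5 Mb, so these counts do not rank density. That of chromosome 17 ended at 78.6 Mb, and that of chromosome 20 held 62 peaks between 60 and 62.4 Mb.

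The 10 Mb stretch of chromosome 11 contained 279 of that chromosome's 567 peaks (49.2%, interval 45.0 to 53.4%). Its density was 27.9 peaks per Mb (24.7 to 31.4), compared with 2.33 (2.07 to 2.61) on the rest of chromosome 11, a ratio of 12.0. The 27.9 is a mean over the stretch, within which peaks were not spread evenly. Clusters of 16, 13, 12, 11 and 10 peaks lay between positions 63520523 and 63904403. With the whole 10 Mb stretch left out, chromosome 11 held 3.96% of the remaining SOX9 peaks (3.53 to 4.44%). Its peaks were mostly weak, since 183 of 279 (65.6%, interval 59.7 to 71.2%) scored below the list median, against 43.4% (37.6 to 49.3%) on the rest of the chromosome. It nevertheless included 25 of the 1000 highest-scoring peaks and 2 of the 10 highest. The input list had 0 peaks in the stretch.

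**Figure D2:**
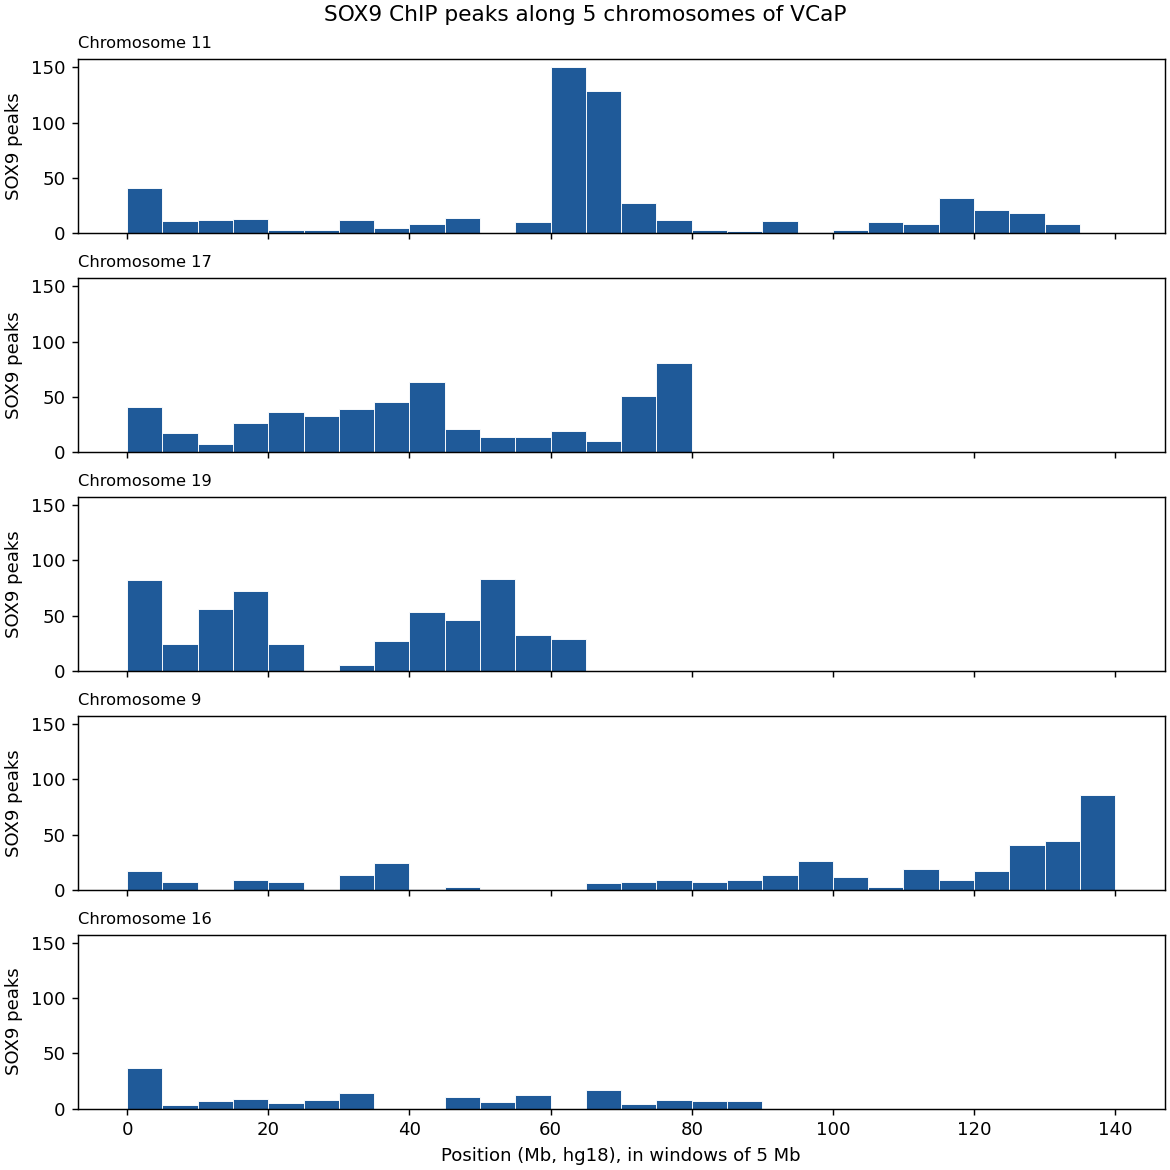
Number of SOX9 ChIP peaks (y axis) in consecutive windows of 5 Mb (x axis, hg18 position in Mb) along chromosomes 11, 17, 19, 9 and 16. The windows from 60 to 70 Mb on chromosome 11 hold 150 and 129 peaks, above the 86 of the fullest window on any other chromosome. The last window of a chromosome covers less than 5 Mb, so its count is not comparable as a density.

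At short range, neighbouring SOX9 peaks were closer together than random placement gave. The median gap between neighbours was 110.1 kb, and 958 of 7522 gaps (12.7%) were under 1 kb, compared with a mean of 41.6 (0.553%) in 100 random placements on the same chromosomes and 74.6 (0.991%) when peaks were redrawn within their own 5 Mb window. Clusters were defined as 3 or more peaks with gaps of at most 12.5 kb. There were 283 such clusters holding 1037 SOX9 peaks (13.7%), whereas random placement gave a mean of 16.6 clusters (range 5 to 28). Most were small, and 198 of the 283 held exactly 3 peaks. When each peak was redrawn only within its own 5 Mb window, so that regional differences in density were kept, a mean of 64.1 clusters (range 46 to 87) was obtained. Merging peaks within 500 bp of each other first lowered the observed number to 130 clusters, and keeping only peaks that scored at or above the median lowered it to 29. The latter filter left 3901 peaks, and random subsets of that many peaks held a mean of 64.9 clusters (range 50 to 81 over 100 draws).

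The largest cluster held 16 peaks over 61.3 kb of chromosome 11 (63734603 to 63795945), the highest with a score of 16.2. A second cluster of 13 peaks spanned 23.5 kb of the same chromosome (63520523 to 63544019), with scores up to 8.33. These clusters contained no peak that overlapped an input peak. Another cluster of 13 peaks, over 26.4 kb of chromosome 2 (132728394 to 132754836), differed in this respect. Of its 13 peaks, 6 overlapped input peaks, and the input list had its own cluster of 16 peaks there (132712778 to 132751105). The next clusters by size were again on chromosome 11. They held 12 peaks (63875054 to 63904403), 11 peaks (63808506 to 63843389) and 10 peaks (63575276 to 63615782). Their highest scores were 120, 123 and 7.81, in that order, and none of their peaks overlapped an input peak.

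A larger share of the input peaks lay in clusters. Of the 393 nuclear input peaks, 244 (62.1%) lay in 38 clusters, whereas random placement gave a mean of 0.006 clusters on whole chromosomes and 0.495 (at most 4) within each peak's own 5 Mb window. The largest input clusters held 21 peaks on chromosome 16 (44943398 to 44993125), 18 on chromosome 10 (41683383 to 41728412) and 17 on chromosome 2 (91632797 to 91687987).

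**Figure D3:**
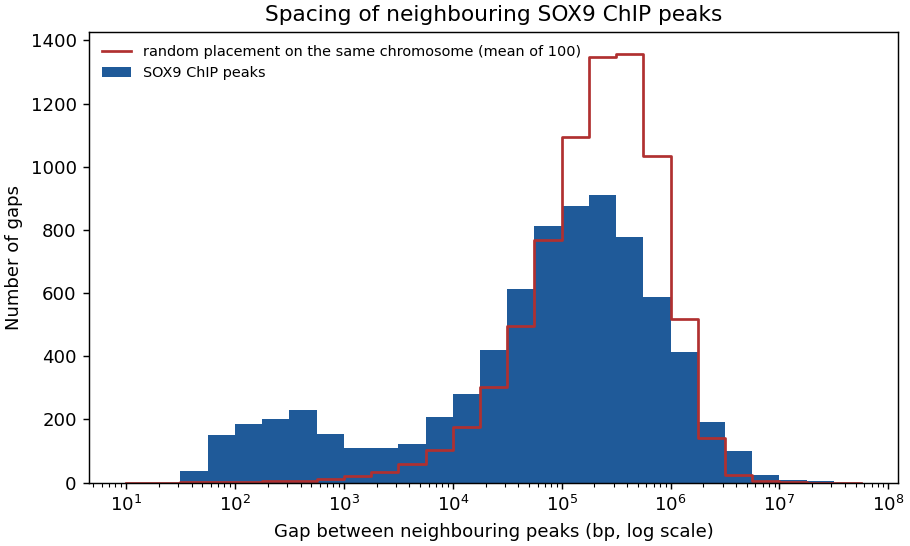
Histogram of the gap between neighbouring SOX9 ChIP peaks (x axis, bp, log scale) against the number of gaps (y axis); bars are the observed gaps and the line is the mean of 100 random placements on the same chromosomes. A separate group of short gaps is seen, with 958 observed under 1 kb and 41.6 under random placement on the chromosome (74.6 within each peak's own 5 Mb window, not drawn).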

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

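Of 156 recomputed values, 125 stayed within the 95% interval of the reported value or, for counts and ratios of counts, within a factor of 1.5. The number of SOX9 peaks stayed between 6785 (peaks within 500 bp merged) and 7539 (nuclear chromosomes only), and that of input peaks between 329 and 393. The share of SOX9 peaks overlapping input fell to 0.371% when 50% of the SOX9 peak had to be covered and to 0.200% among the 1000 highest-scoring peaks, where it rests on 2 peaks, but was 0.718% at or above the median score and 0.610% for centres within 1000 bp. Restriction to peaks at or above the median score moved the share on chromosome 11 to 6.64% and on chromosome 19 to 7.84%. The 1000 highest-scoring peaks gave 11.2% on chromosome 19, 7.90% on chromosome 17 and 0.600% on X. Over all 24 nuclear chromosomes, 12 shares left their interval among the 1000 highest-scoring peaks and 4 at or above the median, whereas none did when peaks overlapping input were removed or neighbours merged. The intervals rest on all 7547 peaks, so shares of 1000 or 3901 peaks leave them more often by counting error alone. Random subsets were not drawn for these shares, so the counts of 12 and 4 do not measure dependence on score. Removing the 40 overlapping peaks could hardly move any share. Leaving out the chromosome 11 stretch, an alternative added after the data had been seen, gave 3.96% for chromosome 11 and 257 clusters. Joining peaks up to 12.5 kb apart, also added later, gave 6.24% for chromosome 11, and the other 23 shares stayed within their intervals. There were 29 clusters at or above the median score, where 3901 peaks were left, against a mean of 64.9 (range 50 to 81) in 100 random subsets of that size, added later, so the shorter list alone accounts for part of the fall. There were 130 clusters after merging within 500 bp, also added later. The ratio of observed to random clusters was 17.02, and it was 8.57 at or above the median score, 7.14 with gaps up to 25000 bp, 46.7 with gaps up to 5000 bp, 10.3 after merging within 500 bp and 4.41 when peaks were redrawn within their own 5 Mb window. It was above 1 under every alternative run. The read depth is unknown, so a limit on detection cannot be set, and with 1 library per group no replicate could be left out. Genomic location, motifs and gene lists were not run.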

Other observations

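The tests of overlap with input and of strong peaks in the chromosome 11 stretch, the test on joined input regions and the choice of the chromosome 21 stretch, were made after the values had been seen. The test on joined regions of chromosome 11 and the test on single input peaks were written before their results were known.

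Chromosome 21 was rich in weak SOX9 peaks. It carries both partners of the TMPRSS2-ERG fusion, but whether any peak lies at these genes was not analysed here. The 177 peaks of chromosome 21 had a median score of 5.93, compared with 7.94 for the list. Of them, 15 (8.47%, exact 95% interval 4.82 to 13.6%) were among the 1000 highest, an interval that includes the 13.3% of the whole list. The weak peaks were gathered in 1 part of the chromosome. Between 42 and 47 Mb, 79 of 103 peaks (76.7%, interval 67.3 to 84.5%) scored below the list median, compared with 33 of 74 (44.6%, 33.0 to 56.6%) on the rest of chromosome 21. The stretch was chosen with the values in view, so this contrast describes it and is not a test. Chromosome 14 had a higher median score of 10.4 over 208 peaks, with 17.8% of them (12.8 to 23.7%) among the 1000 highest. That interval also includes the 13.3% of the whole list.

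Of the chromosome 11 peaks, 49.2% lay between 60 and 70 Mb. A few regions split into many peaks do not account for all of it, since after joining peaks up to 12.5 kb apart the stretch still held 36.4% of the chromosome's 371 joined regions (interval 31.5 to 41.5%). In this list the excess was not made of weak peaks alone. The 1000 highest-scoring peaks were 6.87 times as dense there as on the rest of the chromosome (interval 4.04 to 11.4), and all peaks together 12.0 times. The stretch was chosen for its number of peaks in this same list, and these strong peaks are part of that number. The interval does not cover that choice, so these values describe the list only. Enrichment without antibody stays open: 0 of the 279 peaks there overlapped an input peak, but the input list had no peak in the stretch, so the overlap could not have been higher. A gain of genomic copies in VCaP and a higher density of SOX9 sites are also open, as a peak list measures neither, and no biological explanation was tested.

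Input peaks were crowded, with 62.1% of the nuclear ones in clusters. A candidate explanation is that they gather beside long stretches that yield few mapped reads. The longest gap between neighbouring SOX9 peaks on each chromosome was used as a stand-in for such sequence. Sequence before the first or after the last SOX9 peak was not considered, although on some chromosomes, such as Y, it was longer. Of the 393 nuclear input peaks, 103 (26.2%) lay within 2 Mb of an edge of that gap. Placing single peaks at random ignores their clusters and decides nothing. With neighbours up to 12.5 kb apart joined, 31 of 160 input regions (19.4%, interval 13.6 to 26.4%) lay there, compared with a mean of 11.3 and at most 25 in 1000 random placements. Joining left nearby groups apart, such as those on chromosome 10 at 41683383 to 41728412 and at 41849307 to 41864751. Such regions were placed as if independent, and unassembled sequence was not excluded from the placement. The comparison of joined regions therefore does not decide the explanation either. Inside these gaps lay 72 input peaks (18.3%). A peak inside a gap and within 2 Mb of its edge counts among both the 72 and the 103. The 72 therefore do not speak against the stand-in. Whether the gaps hold unassembled or repeated sequence was not tested.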
